A study of Homo sapiens with 3 samples.

How the data were processed

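Circular RNAs (circRNAs) were measured by RNA sequencing in 3 cell lines: HPDE, a non-tumour pancreatic ductal epithelial line, and PANC-1 and SW1990, lines of pancreatic ductal adenocarcinoma (PDAC). Per the labels' protocols, HPDE grew in keratinocyte serum-free medium with epidermal growth factor and bovine pituitary extract, PANC-1 and SW1990 grew in DMEM with fetal bovine serum, total RNA was extracted with TRIzol, and libraries were made with a NEBNext Ultra RNA kit. There was 1 library per cell line and no replicate, so each line was its own group, and the difference between HPDE and the PDAC lines could not be separated from the difference in medium.

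Per the submitters' processing notes, reads were handled with TopHat2, TopHat and HTSeq on hg19; the notes give no versions. The circRNA caller, its filters and any treatment of ribosomal or linear RNA are not given in the sources used here. Each of the 3 deposited tables lists back-splice junctions by hg19 position. Per the file headers, the values of HPDE and PANC-1 are in RPM (reads per M reads of a library total); the deposited SW1990 table holds the count of back-splice reads, the RPM and a host gene symbol. In each library 100% of the RPM values were whole multiples of the RPM of 1 read within 0.05 reads, and the reads recovered in this way equalled the deposited count for 3764 of 3764 SW1990 circRNAs. The totals behind the authors' RPM were 41.7 M reads for HPDE, 36.7 M reads for PANC-1 and 48.1 M reads for SW1990 (M for mega); which reads those totals count is not stated. The HPDE and PANC-1 tables each hold 1 line whose content had been emptied, and those lines were not analysed here.

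Before the data were examined, an exact binomial test on read counts had been planned for each pair of libraries. Because the HPDE and PANC-1 values are RPM, the main result is instead a fold between the authors' RPM values with no test, and the test is given beside it as an alternative. circRNAs were matched by identical coordinates and had to hold at least 10 reads over the 2 libraries compared. They were called higher or lower at a fold of at least 2. A library at 0 reads was set to a limit of 3 reads for the fold, so such folds are lower bounds against that limit. They do not include the counting error of the other library, and they are no bound where a list lacks a circRNA for a reason other than its read number. Intervals are 95% intervals (Poisson for RPM, Clopper-Pearson for shares, exact conditional binomial for ratios), and they cover counting error only. The added exact conditional binomial test (two-sided, Benjamini-Hochberg over the circRNAs tested, adjusted p under 0.05 and a fold of at least 2) called 4762 circRNAs higher and 1374 lower in PANC-1 against HPDE, 1519 and 1584 in SW1990 against HPDE, and 1225 and 4748 in SW1990 against PANC-1. It compares 2 libraries, not conditions.

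The fold rule and the test were tested on simulated data built from the same read numbers, with 200 changed circRNAs per comparison. Changes of 4-fold were recovered by the fold rule in 95, 93 and 95% of cases for the 3 comparisons in the order above, and by the test in 59, 64 and 61%. Unchanged circRNAs were called by the fold rule in 9.55, 8.71 and 8.63% of cases (0.631, 0.750 and 1.02% of those over 40 reads) and by the test in 0.0308, 0.210 and 0.0308%. The simulated reads varied by counting error only, and no circRNA was missing from a simulated list for another reason. These shares are therefore not the false-call rates of the deposited lists.

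Host genes could be read only from the SW1990 table. Of its circRNAs, 61 had no symbol and 14 had a symbol turned into a date, and 2418 distinct symbols were used. A symbol was passed to a junction of another library that was identical, shared an end, lay within, or overlapped the interval covered by SW1990 junctions of 1 host only. This named 1533 HPDE (45.5%), 5138 PANC-1 (38.5%) and 3691 SW1990 circRNAs (98.1%). With each SW1990 circRNA left out in turn, the shared-end, within and overlap rules gave its own symbol in 829 of 829, 250 of 250 and 175 of 175 cases. Reads summed per host therefore cover only junctions touching the SW1990 interval. Host sums at 0 elsewhere do not show that a gene had no circRNA there, and folds of SW1990 over another library are biased upward.

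The lists of host genes were fixed by symbol; 1 of the 19 lists and some single hosts are not reported here. The others were: PDAC driver genes; chromatin regulators; epithelial and basement-membrane adhesion genes; mesenchymal and extracellular-matrix genes; TGF-beta, WNT and Hippo signalling; receptor kinase, RAS and PI3K signalling; cell cycle, mitosis and centrosome; DNA replication and repair; ubiquitin ligases and deubiquitinases; RNA-binding and splicing factors; nuclear pore and nuclear transport; vesicle traffic and endocytosis; hosts of widely reported circRNAs; hosts of circRNAs reported in pancreatic cancer; and fibroblast and stellate, immune, endothelial, and acinar, islet and neural cell genes. For lists with at least 5 hosts of at least 10 reads, the median log2 fold was placed as a percentile among 10000 random lists of the same size matched on mean RPM in 10 bins. These percentiles describe the libraries and are not p-values.

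The rule for named features was, per comparison, the 8 largest folds in each direction; the 5 circRNAs with most reads per library; the 8 circRNAs called the same way in both PDAC lines with the largest smaller fold, per direction; and up to 4 hosts with most reads from each list. A FOXK2 circRNA was also named, because a study of these lines followed a circRNA of this gene; the tables give no circRNA identifier, so the match of the junction was not checked, and it is not independent evidence. Because the largest folds are lower bounds at circRNAs found in a single library, circRNAs with reads on both sides were added after their values were seen, and the text says where.

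The alternatives tried were scaling to total back-splice reads, median of ratios, and TMM factors (edgeR 4.0.16, R 4.3.3, used for these factors only); no read filter or at least 20 reads; a fold of at least 4; the lower end of the interval at least 2; reads summed per host; junctions within 5 bases merged; thinning to equal reads (20 draws); detection from 2 or 5 reads; and 0.5 reads added to every value. Those added later are named with their results. The simulation of libraries sharing HPDE was run 50 times. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Junctions without a host symbol were kept in all counts, as single features where reads were summed per host as an alternative, and left out of host lists. Linear RNA and raw reads were not analysed here.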

Results

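Back-splice junction reads were compared between 3 human cell lines with 1 library each: the non-tumour ductal line HPDE and the PDAC lines PANC-1 and SW1990. The HPDE list held 3370 circRNAs with 1408352 back-splice reads, the PANC-1 list 13341 with 1885511 reads, and the SW1990 list 3764 with 1273083 reads. The median circRNA had 13, 6 and 10 reads in that order, and 1 read corresponded to 0.0240, 0.0273 and 0.0208 RPM. With no replicates, intervals cover counting error only, and a difference between libraries is not a tested difference between conditions.

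Junctions within RPPH1, the gene for the RNA part of RNase P, took most of the reads in every library: 78.4% in HPDE, 71.7% in PANC-1 and 74.5% in SW1990. They came from no more than 4 listed junctions per library, and the most abundant differed: 14:20811249-20811419 in HPDE (485554 reads), 14:20811288-20811566 in PANC-1 (1351950) and 14:20811276-20811566 in SW1990 (948706). The ribosomal RNA scaffold held a further 2.82, 6.70 and 9.62% of reads and the mitochondrial genome 0, 0.617 and 0.0744%. Together these loci held 81.2, 79.0 and 84.2% of reads but only 1.16, 3.41 and 1.70% of circRNAs. Outside them, junctions spanning under 500 bases made up 15.4% of HPDE circRNAs (95% interval 14.2 to 16.7%), 8.97% in PANC-1 (8.48 to 9.48%) and 17.0% in SW1990 (15.8 to 18.2%), and 32.5, 25.8 and 47.0% of the reads. Among them were histone and ribosomal protein transcripts: in SW1990, HIST1H4B reached 263 RPM, HIST1H1C 234 RPM, RPS2 71.2 RPM and RPL13 68.1 RPM, each from a junction with no reads in the other libraries. The host could still be shared: in PANC-1 a different HIST1H1C junction, at 6:26056069-26056299, reached 233 RPM. The median genomic span of all junctions was 2937.5 bases in HPDE, 6231 in PANC-1 and 3051.5 in SW1990.

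Most circRNAs were found in a single line. Of 17156 distinct circRNAs, 659 were in all 3 lists, 1001 in both PDAC lists and not in HPDE, 10899 in PANC-1 only, 1886 in SW1990 only and 1711 in HPDE only. PANC-1 held 42.8% of the HPDE list and 44.1% of the SW1990 list, and SW1990 held 26.0% of the HPDE list. High read numbers did not bring full overlap: of PANC-1 circRNAs with at least 100 reads, 22.9% (19.3 to 26.7%) were found in HPDE and 21.5% (18.1 to 25.3%) in SW1990. Thinned to 200920 reads outside those loci, the lists held 3274, 11561 and 3700 circRNAs for HPDE, PANC-1 and SW1990. circRNAs with at least 20 reads in both other libraries were found in PANC-1 for 81.4% of 279, in HPDE for 60.5% of 372 and in SW1990 for 60.2% of 364, so absence from a list, at HPDE and SW1990 above all, is weak evidence that the circRNA was not made.

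**Figure D1:**
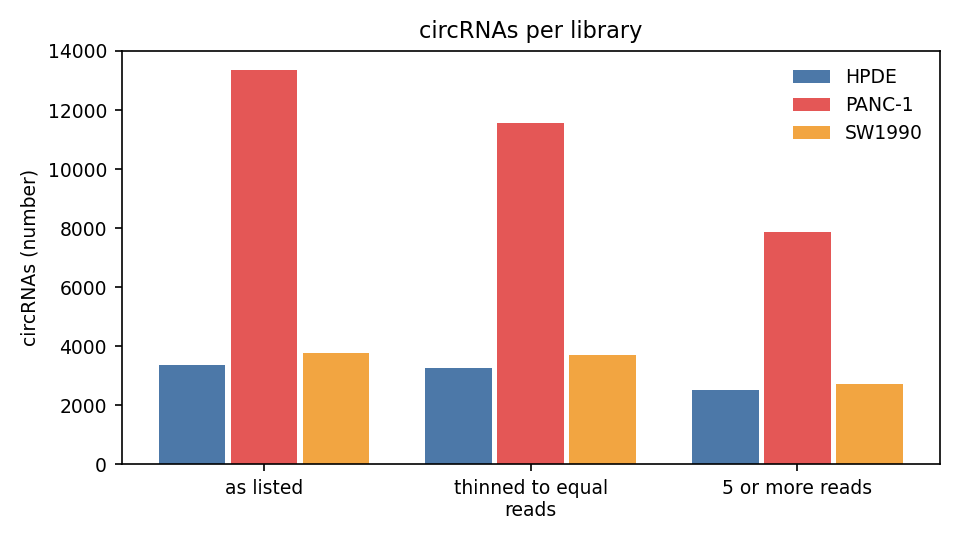
Number of circRNAs listed in each library (bars, linear axis from 0; HPDE, PANC-1 and SW1990), as listed, after thinning to equal reads, and with 5 or more reads. PANC-1 holds 13341 circRNAs as listed, against 3370 in HPDE and 3764 in SW1990.

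Against HPDE, PANC-1 carried much higher levels of several circRNAs known from other cell types and cancers. The ZNF609 circRNA, from a zinc-finger gene whose circRNA is known from muscle cells, was at 29.3 RPM in PANC-1 and 1.85 RPM in HPDE, 15.9-fold higher (12.6 to 20.3). The RTN4 circRNA, from a gene of endoplasmic reticulum shape, was 17.5-fold higher (14.0 to 22.1). Summed over their junctions, the chromatin remodelling gene BAZ1B was 64.6-fold higher (35.9 to 130), the importin IPO7 52.2-fold (30.9 to 96.1), the focal adhesion protein TNS3 26.5-fold (18.3 to 39.9), and the focal adhesion kinase PTK2 13.0-fold (9.45 to 18.2). ZEB1, a repressor of epithelial genes, was 36.1-fold higher on 4 HPDE reads (13.8 to 135). Reads at FBXW7, a ubiquitin ligase subunit mutated in several tumour types, and at TNPO3 and PRKDC were absent in HPDE, and these hosts were at least 108-, 80.7- and 58.8-fold higher in PANC-1.

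Several single hosts were lower in PANC-1. Host sums of the integrin ITGB4, which anchors epithelium to the basement membrane, were 9.93 RPM in HPDE with no PANC-1 read at its SW1990 interval, at least 121-fold lower. The AXL ligand GAS6 and the p120 catenin gene CTNND1, also with no PANC-1 read at their SW1990 intervals, were at least 51.9- and 45.7-fold lower. TGFBR2, a TGF-beta receptor mutated in some PDAC, was 16.7-fold lower (6.26 to 62.9). RANGAP1 was 4.16-fold lower (3.26 to 5.35), AXIN1 2.88-fold (2.26 to 3.72) and RBM39 2.59-fold. Chosen after their values were seen, as circRNAs with reads on both sides, the circRNA of the interferon-induced gene IFI6 was at 166 RPM in HPDE and 2.54 RPM in PANC-1, 65.4-fold lower (53.3 to 81.1), that of the nuclear lamin LMNB2 was 64.4-fold lower (32.5 to 150), and that of TNFRSF21 was 81.0-fold higher (31.3 to 299). ERBB2 was level (ratio 0.934, 0.761 to 1.15), as were SF3B3 (1.02) and WWC1 (1.10).

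Over all 6701 circRNAs compared, 4827 were higher in PANC-1, 1414 lower and 460 within 2-fold; 4379 of them had reads in PANC-1 only and 1053 in HPDE only. Among the 1269 with reads in both libraries the split was nearly even, 448 higher and 361 lower, with a median log2 fold of 0.26. Other scalings shifted all log2 folds by -0.61 (total back-splice reads), -0.29 (TMM) and -0.22 (median of ratios), which took this median to -0.35, -0.03 and 0.03, so its sign depends on the scaling. Outside RPPH1 and ribosomal RNA, whose junctions gave the largest lower bounds in both directions, the next belonged to PANC-1 junctions with no host name, at 6:26188987-26189229 (568 RPM), 11:65268834-65273125 (441 RPM) and 17:80193859-80195769 (309 RPM). In the other direction stood HPDE junctions, also with no host name, at 17:39780459-39780716 (687 RPM), X:153578084-153592732 (435 RPM) and 12:52910891-52914092 (310 RPM). Hosts were named through SW1990 only, so these unnamed junctions may still lie in genes, including genes of the host lists.

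Host lists for PANC-1 against HPDE mostly followed the median of all 1585 hosts, a log2 fold of 2.06 (1053 higher, 181 lower, 351 within 2-fold). Vesicle traffic genes lay above it (median 2.86, percentile 98.94; 20 higher, 1 lower, 5 within), with ASAP1 at 10.5-fold and ASAP2 at 8.28-fold higher. Hosts of widely reported circRNAs did too (30, 1 and 7 hosts, median 2.39, percentile 97.71). Among them ZKSCAN1 was 7.23-fold higher and SETD3, also on the chromatin regulator list, 5.38-fold higher. Neither list stayed outside the central 95% when random lists were also matched on the length of the host interval (percentiles 96.86 and 96.04). The epithelial list was low but inside that range (0.15, percentile 3.03; 4, 4 and 2), and its median changed sign to -0.08 under median-of-ratios scaling. With interval length matched it stood at percentile 2.09, outside that range. Lists inside it were PDAC drivers 1.99 (7, 1 and 1), chromatin 1.77 (17, 0 and 10), TGF-beta, WNT and Hippo 2.51 (17, 2 and 2), receptor kinase 1.97 (15, 0 and 7), cell cycle 1.48 (18, 2 and 7), DNA repair 1.86 (13, 3 and 4), ubiquitin 2.30 (26, 3 and 4), RNA-binding 2.19 (21, 1 and 11), nuclear transport 2.09 (11, 1 and 6) and hosts reported in pancreatic cancer 1.92 (14, 1 and 3).

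SW1990 shared only part of that profile against HPDE. Host sums of SMARCA4, the ATPase of SWI/SNF chromatin remodelling, were 20.2-fold higher (9.57 to 51.0), ZEB1 7.80-fold (2.79 to 30.2), IPO7 5.57-fold (3.15 to 10.6), the replication ligase LIG1 5.51-fold (3.68 to 8.52), the Hippo regulator WWC1 4.68-fold (3.20 to 7.06) and UHRF1, which maintains DNA methylation, 3.76-fold (2.99 to 4.79). KRT7, a ductal keratin, and MMP14, a membrane-bound matrix protease, had no HPDE reads at their SW1990 intervals and were at least 150- and 185-fold higher. The RTN4 circRNA was 2.95-fold higher (2.30 to 3.82), whereas that of ZNF609 was 1.74-fold lower (1.21 to 2.53). Lower host sums included the centrosomal gene CEP70 at 5.66-fold (2.83 to 12.5), RBM39 at 3.82-fold (3.11 to 4.71), RANGAP1 at 3.32-fold (2.72 to 4.08), TGFBR2 at 2.83-fold (1.84 to 4.45) and HUWE1 at 2.78-fold (1.87 to 4.19). ITGB4 (ratio 1.06, 0.930 to 1.21), CTNND1 (1.07, 0.863 to 1.33) and ERBB2 (1.01, 0.840 to 1.22) were level in their host sums. The level sum of ITGB4 held unlike junctions: that at 17:73738422-73738842 had 246 SW1990 reads against 2 in HPDE (ratio 107, 29.2 to 885).

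Individual SW1990 circRNAs with reads on both sides, chosen after their values were seen, included a junction of the translation factor EIF4B with 382 reads against 2 in HPDE (ratio 165, 45.5 to 1371) and a junction of the histone demethylase KDM1A with 101 against 3 (29.2, 9.70 to 144). The circRNA of the mitotic kinase AURKA had 2 reads against 75 (43.3 times lower, 11.6 to 364). The IFI6 circRNA was 3.52-fold lower (3.35 to 3.69). Of 3541 circRNAs, 1559 were higher, 1618 lower and 364 within 2-fold, 1396 and 1368 of them found in SW1990 only or HPDE only; of the 777 in both, 163 were higher and 250 lower, with a median log2 fold of -0.21. Scaling shifts were 0.35 (total), 0.22 (TMM) and 0.23 (median of ratios), which took this median to 0.15, 0.01 and 0.02. Total scaling gave 1604 higher and 1566 lower, and median of ratios 1584 and 1581, so neither direction prevailed under every scaling.

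**Figure D2:**
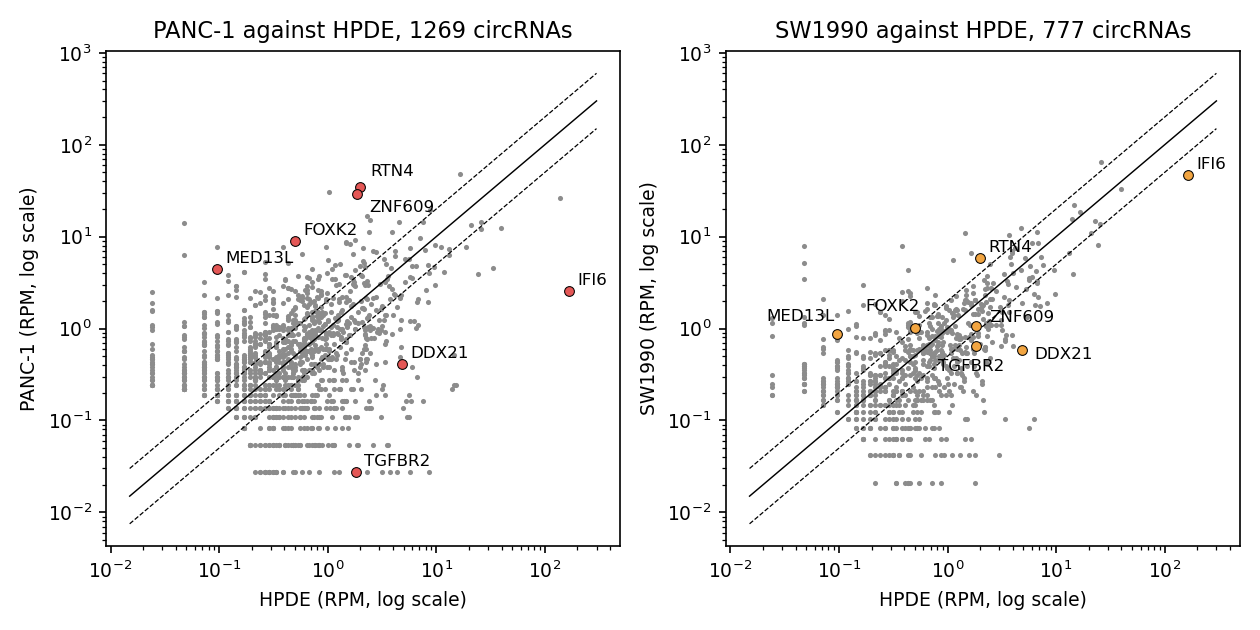
RPM of circRNAs with reads in both libraries of each comparison and at least 10 reads over them (points; log axes); the solid line marks equal RPM and dashed lines 2-fold. Of 1269 such circRNAs in HPDE and PANC-1, 448 lie over 2-fold higher in PANC-1, and of 777 in HPDE and SW1990, 163 lie over 2-fold higher in SW1990.

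In the host lists for SW1990 against HPDE the median of all 1788 hosts was 1.67 (1052 higher, 258 lower, 478 within), a value raised by naming hosts from SW1990. Ubiquitin genes lay below it (0.38, percentile 1.93; 11 higher, 8 lower, 10 within), with HUWE1 lower, but stood at percentile 5.35 once interval length was matched. No other list was outside the central 95%. The mesenchymal list, with 5 hosts, was at 1.58 (3, 0 and 2), the epithelial list at 2.11 (11, 1 and 3), TGF-beta, WNT and Hippo at 2.22 (14, 2 and 2), receptor kinase at 0.21 (8, 6 and 7), cell cycle at 0.95 (14, 5 and 10) and hosts reported in pancreatic cancer at 1.56 (12, 0 and 7). The naming limits each list: of the 52 epithelial genes 16 were named, and a host with HPDE reads but no SW1990 junction could not enter. Counts of higher and lower hosts therefore leave out hosts found in HPDE only.

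Epithelial and ubiquitin hosts split the PDAC lines in opposite directions. Of 15 epithelial hosts, 10 were higher in SW1990, 3 lower and 2 within 2-fold of PANC-1 (median log2 3.15, percentile 99.99), and all 10 had no PANC-1 read at their SW1990 interval: the adherens junction cadherin CDH1 (43 SW1990 reads), EPCAM (38), the epithelial splicing factor ESRP1 (41), the transcription factor GRHL2 (90), KRT7 (520), the laminin LAMA3 (33), ITGB4 (507), ITGA6 (15), CTNND1 (193) and MPP5 (35). Once PANC-1 had no read, these 10 calls were fixed by the rule, since at least 10 reads against the 3-read limit always give a fold over 2. Each host also entered only through an SW1990 junction. ITGB4 was at least 129-fold and KRT7 at least 132-fold higher. LAMA5 (1.29-fold, 1.14 to 1.46) and ITGA3 were within 2-fold, and PKP4, TJP1 and PARD3 were lower. Here ZEB1 circRNAs were 4.63-fold lower in SW1990 (3.18 to 6.91), while MMP14 was at least 162-fold and GAS6 at least 45.2-fold higher. At the SW1990 intervals of the 10 epithelial hosts above, HPDE also carried reads for EPCAM (7), GRHL2 (19), LAMA3 (51), ITGB4 (414) and CTNND1 (156), but none for the other 5. Over the 15 epithelial hosts, 7 had no HPDE read at their SW1990 interval.

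Ubiquitin ligase and deubiquitinase hosts went against the upward bias that naming hosts from SW1990 brings, with 3 of 36 higher in SW1990, 23 lower and 10 within 2-fold (median log2 -1.96, percentile 0.00). RNF13 was 37.5-fold lower (20.1 to 79.1), HUWE1 5.32-fold (3.69 to 7.85) and the apoptosis inhibitor BIRC6 4.36-fold (3.22 to 5.99). Hosts of widely reported circRNAs were also lower (2, 23 and 15 hosts, median -1.56, percentile 0.13). That list shares RNF13, BIRC6 and ITCH with the ubiquitin list, so the results are not independent. It also held ZNF609 at 27.7-fold lower (20.9 to 37.4) and ZKSCAN1 at 6.07-fold (5.02 to 7.38). PTK2, also on the receptor kinase list, was 5.11-fold lower (4.19 to 6.28). Outside these lists, BAZ1B was 137-fold lower (62.5 to 374), FBXW7 23.5-fold (14.2 to 41.6), CEP70 20.7-fold (10.99 to 44.1), the Fanconi anaemia ligase FANCL 12.3-fold (8.63 to 18.1), IPO7 9.38-fold (7.51 to 11.8) and TNS3 8.89-fold (7.20 to 11.1). Higher in SW1990 were UHRF1 at 6.08-fold (4.51 to 8.36), TGFBR2 at 5.90-fold (2.09 to 23.0), WWC1 at 4.25-fold (2.89 to 6.45) and SMARCA4 at 3.27-fold (2.28 to 4.78).

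With random lists also matched on interval length, the epithelial, ubiquitin and widely reported lists stood at percentiles 99.98, 0.07 and 0.65. The median of all 2061 hosts was -0.49 (566 higher, 819 lower, 676 within), and other lists stayed inside the central 95%: PDAC drivers -1.14 (4, 6 and 1), chromatin -0.69 (4, 11 and 15), DNA repair -0.85 (3, 11 and 8), RNA-binding -0.61 (4, 13 and 21), nuclear transport -0.88 (2, 11 and 10) and vesicle traffic -1.08 (3, 16 and 12). Of 6687 circRNAs, 1302 were higher in SW1990, 4814 lower and 571 within 2-fold, 998 and 4246 of them found in a single library; of the 1443 in both, 304 were higher and 568 lower, with a median log2 fold of -0.54. Scaling shifts were 0.96 (total), 0.51 (TMM) and 0.50 (median of ratios), which took this median to 0.41, -0.04 and -0.05.

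**Figure D3:**
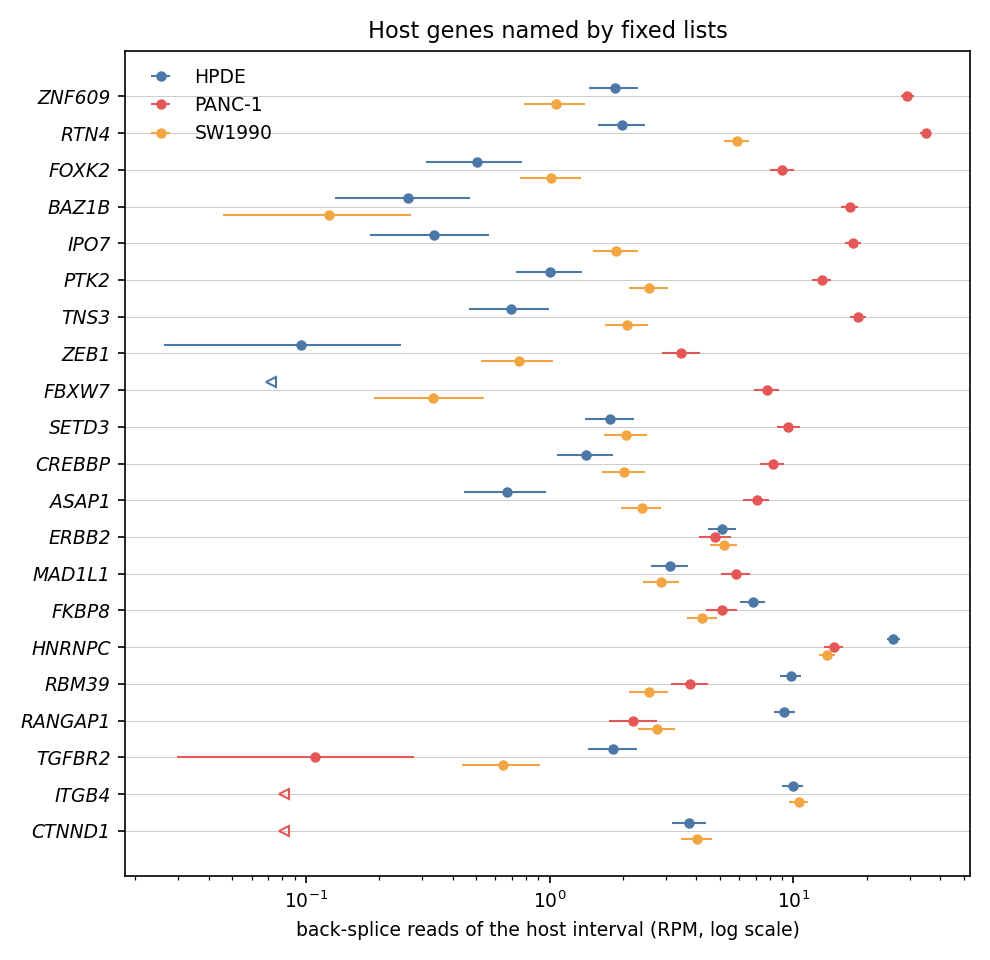
RPM of back-splice reads summed per named host gene in HPDE, PANC-1 and SW1990 (points with bars for the 95% Poisson interval; log axis); open left-pointing triangles mark the 3-read limit of a library at 0 reads. ITGB4 lies at 9.93 RPM in HPDE and 10.5 RPM in SW1990 and at the limit in PANC-1.

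Some circRNAs were higher in both PDAC lines than in HPDE. Among those with no HPDE reads, the circRNA of the amyloid precursor APP was at least 108-fold higher in PANC-1 and 236-fold in SW1990, that of the laminin LAMA5 at 20:60885721-60886150 at least 80.4- and 98.7-fold, of the myosin MYO18A at least 108- and 69.6-fold, of ferritin heavy chain FTH1 at least 128- and 63.8-fold, and of glycogen phosphorylase PYGB at least 101- and 59.2-fold; LRRC47, GANAB and DHX34 completed the top 8. Over all its junctions LAMA5 differed far less, 1.61-fold higher in PANC-1 (1.38 to 1.89) and 2.08-fold in SW1990 (1.81 to 2.39). With HPDE reads, and chosen after their values were seen, the circRNA of the collagen-folding enzyme P4HB was 19.97-fold higher in PANC-1 (12.1 to 35.4) and 20.8-fold in SW1990 (12.6 to 36.7), that of the Mediator subunit MED13L 46.6-fold (17.9 to 173) and 9.10-fold (3.30 to 34.9), and that of MBOAT2 15.4-fold (6.76 to 43.1) and 7.80-fold (3.36 to 22.2). Lower in both, also chosen after the values were seen, were the circRNAs of alanyl-tRNA synthetase AARS at 16:70294947-70296427 (29.6-fold, 14.2 to 74.5, and 68.1-fold, 26.3 to 252), EXOC7 (17.8-fold, 8.44 to 45.2, and 32.8-fold, 13.7 to 103), the arginine methyltransferase PRMT5 (13.2-fold, 4.89 to 50.0, and 13.9-fold, 5.62 to 44.2) and the helicase DDX21 (11.9-fold, 7.05 to 21.7, and 8.37-fold, 5.62 to 12.9).

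The FOXK2 circRNA at 17:80521230-80526077, from a forkhead transcription factor, was at 0.504 RPM in HPDE (0.312 to 0.770), 9.0 in PANC-1 (8.05 to 10.0) and 1.02 in SW1990 (0.753 to 1.35). It was 17.9-fold higher in PANC-1 than in HPDE (11.5 to 29.3) and 2.02-fold higher in SW1990 (1.19 to 3.55), an interval that reaches below the 2-fold threshold. A study of these lines followed a circRNA of this gene; the tables give no circRNA identifier, so whether it is this junction was not checked, and the values are not independent evidence. MYOF hosts, also on the pancreatic cancer list, were 3.48-fold (2.69 to 4.55) and 2.69-fold (2.08 to 3.51) higher.

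Of 2406 circRNAs compared in both PDAC lines, 429 were higher in both, 1274 lower in both and 95 opposite. Independent lists would share 116.3 and 938.9, and simulated unchanged PDAC libraries set against the shared HPDE library gave 110.1, 105.4 and 0.8. Of the 429, 341 had no HPDE reads, and of the 1274, 928 had no reads in either PDAC line. These calls were fixed by the rule, since at least 10 reads set against the 3-read limit always give a fold over 2. The simulation drew reads by counting error alone and held no other gaps in the lists. The excess over both expectations in the full counts therefore does not show a shared change. Among 572 circRNAs with reads in all 3 libraries, 88 were higher in both, 90 lower in both and 29 opposite; the covariance of their log2 folds was 1.88 against 0.113 in the simulation, and the correlation, across circRNAs that are not independent replicates, was 0.52 against 0.50. The single HPDE library cannot be split, so part or all of the excess may come from it. These values therefore do not show a change shared by the PDAC lines.

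Hosts typical of other cell types were almost absent. COL3A1 was the only fibroblast or stellate cell host, with 2 SW1990 reads, and PTPRN2 the only acinar, islet or neural host, with 4 PANC-1 and 3 SW1990 reads. No host of the 20 immune or 11 endothelial genes was named, although hosts could be named only through SW1990.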

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

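The ratio of list lengths without the RPPH1, ribosomal and mitochondrial loci was a test chosen only after the result was seen. The other tests of list length here had their prediction written before their result. Thinning outside those loci was nevertheless an alternative chosen after the data were seen.

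Host sums of 3 named genes with reads in all 3 libraries differed from HPDE in opposite directions in the PDAC lines, by more than 2-fold of RPM each way. BAZ1B had a log2 fold of 6.01 in PANC-1 and -1.08 in SW1990, CEP70 of 1.87 and -2.50, and FANCL of 2.55 and -1.07. LIG1 also went opposite ways, with 28 HPDE reads and 178 in SW1990 (5.51-fold higher). It had no PANC-1 read at its SW1990 interval (at least 8.21-fold lower against the 3-read limit). The difference between the lines was not tested, since each line has 1 library. These calls of BAZ1B and FANCL depend on the scaling: with total, TMM and median-of-ratios scaling the SW1990 log2 fold was -0.73, -0.87 and -0.86 for BAZ1B and -0.72, -0.86 and -0.85 for FANCL, under 2-fold, while CEP70 was at -2.15, -2.28 and -2.27. The SW1990 values of BAZ1B (6 reads against 11 in HPDE) and FANCL (34 against 62) lie close to the threshold, with ratio intervals of 0.143 to 1.39 and 0.303 to 0.733, and no explanation was tested for these genes.

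The PANC-1 list was about 4 times as long as the others. More back-splice reads are argued against, since the list was still 3.531 times the HPDE list at equal reads outside the abundant loci, and so are junctions at those loci, since the ratio without them was 3.869. A candidate explanation that remains is that fewer distinct molecules were sampled in HPDE and SW1990: circRNAs well covered in both other libraries were found in PANC-1 more often by at least 20.878 percentage points. That gap was predicted for uneven sampling, but a larger circRNA repertoire in PANC-1 could give it too, so it favours neither. It also need not account for the whole ratio. The share of PANC-1 circRNAs found in HPDE was 3.85% at 1 read, 21.2% at 50 to 99 reads and 22.9% at 100 or more. In SW1990 it was 4.47, 22.9 and 21.5%. Most PANC-1 circRNAs with many reads were thus missing from each other list, and the cause was not tested. A larger circRNA repertoire in PANC-1 stays open and untested, as does a difference in library preparation that the labels do not describe.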

How the results depend on the processing

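The exact test on recovered or halved reads, leaving out the abundant loci, thinning outside those loci, restriction to circRNAs with reads in every library and matching on interval length were chosen after seeing the data. No paired analysis was possible because the libraries come from 3 unrelated lines, and leaving out a replicate was not possible with 1 library per line. No list median outside the central 95% changed sign under the alternatives run. List medians inside it did under median of ratios: epithelial hosts in PANC-1 against HPDE (0.145 to -0.078) and hosts reported in pancreatic cancer in SW1990 against PANC-1 (-0.375 to 0.121). Of the values that answer a comparison, 128 stayed within their bounds and 30 moved; of the list medians, 168 stayed and 3 moved, all upward with 0.5 reads added: TGF-beta, WNT and Hippo to 5.043 in PANC-1 and 4.837 in SW1990 against HPDE, and hosts reported in pancreatic cancer to 4.124 in PANC-1 against HPDE. The read filter sets how many circRNAs can be counted. With no read filter, 3180 were lower in PANC-1 than in HPDE, 2993 higher and 7315 lower in SW1990 than in PANC-1, and 737 higher in both PDAC lines. With at least 20 reads, 2724 were higher in PANC-1 and 955 in SW1990 than in HPDE, 841 higher and 2755 lower in SW1990 than in PANC-1, and 202 higher in both. Restriction to reads in both libraries leaves fewer circRNAs by construction: 448 higher and 361 lower, 163 and 250, and 304 and 568 in the 3 comparisons, and 88 and 90 in both PDAC lines with reads in all 3; the PANC-1 excess over HPDE thus rests on circRNAs absent from the HPDE list. With named junctions summed per host and the others kept singly, 586 were higher in SW1990 than in PANC-1. With at least 5 reads, PANC-1 listed 7875 circRNAs and both PDAC lines without HPDE shared 656. The share at the RPPH1, ribosomal and mitochondrial loci was 81.2, 79.0 and 84.2% of reads, and 0.636, 0.648 and 0.666% of circRNAs with at least 5 reads. The lists outside the central 95% for PANC-1 against HPDE numbered 0 with at least 20 reads, 0 with 0.5 reads added and 1 (epithelial, percentile 2.09) with interval length matched; for SW1990 against HPDE they numbered 0 with interval length matched. The cause was not tested where the construction does not show it. With 20 reads as the host minimum, 1 list was too small to give a value. Depth limits circRNAs under 10 reads, and a 0 in HPDE or SW1990 is a limit, not absence.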

Other observations

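The comparisons of short junctions within each library and with at least 10 or 100 reads, the resampling of chromosome 19 windows, and the tests of abundant junctions and of high values in every line for the window of chromosome 19 from 40 to 42 Mb, were chosen only after results were seen.

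Several hosts gave many different circRNAs in PANC-1. PTK2 had 39 junctions there against 4 in HPDE and 8 in SW1990, and the drug transporter ABCC1 31 against 7 and 8. MAD1L1, a spindle checkpoint gene, was more even, with 12 in HPDE, 20 in PANC-1 and 14 in SW1990. Read sums did not follow junction numbers in each case: AFAP1 had 18 PANC-1 junctions against 1 in HPDE but 59 reads against 65. These hosts were chosen after their values were seen.

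Even read numbers outnumbered odd ones among circRNAs with few reads: 1108 circRNAs with an even number from 2 to 20 reads against 970 with an odd number from 1 to 19 in HPDE, 5275 against 5220 in PANC-1, and 1441 against 1142 in SW1990. circRNAs with 2 reads outnumbered those with 1 read: 322 against 158 in HPDE, 1961 against 1612 in PANC-1 and 408 against 191 in SW1990. That gap exceeds the whole even excess in HPDE and PANC-1, so no general even pattern is shown there. In SW1990 the excess is larger than the gap.

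Short junctions took a large part of the reads, and a hypothesis was that junctions of abundant short RNAs may be joined by other means than back-splicing. Outside RPPH1, ribosomal and mitochondrial RNA, junctions under 500 bases recurred in another library in 14.859% of cases (13.3 to 16.5%) and longer ones in 16.1% (15.5 to 16.7%), intervals that overlap. This pooled share mixes libraries that differ in recurrence. Within HPDE, 38.986% of short junctions (34.7 to 43.4%) recurred against 51.7% of longer ones (49.8 to 53.6%), and within SW1990 34.713% (31.0 to 38.6%) against 53.8% (52.1 to 55.6%), the deficit that the hypothesis needs. Within PANC-1 the shares were 21.28% (18.95 to 23.8%) and 18.7% (18.0 to 19.4%), which does not decide. Pooled over circRNAs with at least 10 reads they were 24.7% (21.8 to 27.6%) and 27.1% (26.0 to 28.2%), and with at least 100 reads 21.0% (15.8 to 27.0%) and 32.6% (29.3 to 35.98%), where the intervals do not overlap. Within libraries at 100 reads the deficit stood in SW1990 alone (26.0%, 17.9 to 35.5%, against 50.5%, 43.1 to 57.98%), with overlapping intervals in HPDE and PANC-1. At 10 reads it stood in HPDE (41.1%, 35.3 to 47.1%, against 54.4%, 51.9 to 56.8%) and SW1990 (40.1%, 34.7 to 45.6%, against 59.2%, 56.7 to 61.6%). PANC-1 ran the other way at 10 reads, with overlapping intervals (31.3%, 27.0 to 35.9%, against 26.5%, 25.3 to 27.8%). Short circRNAs specific to a line, or called less reliably, would leave the same deficit and were not tested.

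PANC-1 circRNAs on chromosome 19 between 38 and 42 Mb had high values, and no tested explanation could be decided. By median PANC-1 RPM the window from 38 to 40 Mb lay at percentile 98.55 of all windows and that from 40 to 42 Mb at 87.74, but resampling their circRNAs gave 95% intervals of 6.66 to 100 and 16.6 to 100. These values therefore argue neither for nor against 1 or 2 very abundant junctions or a gain covering both windows. The 2 most abundant junctions held 33.59% of the PANC-1 RPM of the window from 38 to 40 Mb and 37.84% of that from 40 to 42 Mb. A region with high values in every line stays open as well. The window from 38 to 40 Mb lay at percentile 81.38 in HPDE (59.5 to 98.8) and 12.47 in SW1990 (1.05 to 96.1). For the window from 40 to 42 Mb PANC-1 differed from the higher of the other libraries by -3.4 points. Summed RPM was higher in PANC-1 than in HPDE and SW1990: 274 against 6.71 and 5.65 from 38 to 40 Mb, and 111 against 23.5 and 12.5 from 40 to 42 Mb. The smallest of these ratios was 2.77 times the same ratio over all windows. The sums were not resampled, so they do not settle the question. A difference in splicing at a few genes was not tested.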
